A study of Glycine max with 6 samples.

How the data were processed

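Leaf transcripts of soybean (Glycine max, cultivar OAC Bayfield) were measured on 6 Affymetrix soybean arrays, a 1-colour design in which biotin-labelled cRNA was hybridised. The deposited values are 1 number per probe set and array. They were made by the authors with RMA, per the submitters' processing notes; the version and the software are not given in the sources used here. RMA corrects background, puts all arrays on 1 distribution and summarises the probes of a probe set. The scale of the deposited table is not stated either, and was taken as log2 because values over the 6 arrays ran from 1.45 to 14.6, with medians per array from 3.42 to 3.47. The values are not centred by probe set. All 6 columns of per-sample values were used.

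The 3 water arrays and the 3 LCO arrays were grouped from their titles. The array carries 61170 probe sets, of which 37593 have soybean identifiers, 15864 belong to the oomycete Phytophthora sojae and 7530 to the soybean cyst nematode Heterodera glycines, 135 are manufacturer's controls and 48 are soybean ribosomal RNA. Of the soybean probe sets, 8677 are paired with 1 gene in the platform annotation, 370 with several and 28546 with none in the table used, so those are unnamed here, which is not the same as having no gene. Symbols were updated through the Entrez identifier to the RefSeq genes of assembly Glycine_max_v4.0, where 8652 of the 8677 probe sets with 1 gene matched; no coordinates are given because the array's own build is not stated. No gene was named from a probe set paired with several genes.

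Soybean probe sets were tested where their mean over the 6 arrays lay above the percentile 90 of the means of the 23394 probe sets of the other organisms, which was a log2 value of 3.31. That left 29286 probe sets. Differences between LCO and water were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with its default prior, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design was completely randomised per the labels, and nothing in the sources says that replicates came from separate plants or pools, so p-values measure only the spread between these samples, which may be technical. Water 1 and water 2 were compared for being a single sample deposited again. They were the closest pair, with 65 values of the tested probe sets equal to every deposited digit, against 17 to 50 in the other pairs. The difference between them was correlated between different probe sets of the same gene (Pearson r = 0.615 across 745 genes, which are not independent replicates), and they were counted as separate samples.

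Where every array of the dimmer group lay under 3.31, the fold is given as a lower bound: the mean of the brighter group against that value. The number of arrays limits the precision.

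Gene lists were tested with camera at its preset inter-gene correlation, over lists with at least 5 tested probe sets. A set of 49 lists was written before the data were examined; since the tables pair probe sets with symbols and synonyms but no descriptions, only 17 of these reached 5 probe sets. A further 46 lists by gene symbol were written after the symbols had been read and before any test, and 44 reached 5 probe sets. Members past the threshold were counted over all probe sets tested and adjusted over the list alone. The test, the alternatives and the rule for named genes were also fixed before the data were examined.

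The rule for named genes took, among changed probe sets whose groups did not overlap and which have exactly 1 gene with an informative name, the 12 largest rises and the 12 largest falls, with the brightest probe set per gene. It also took, per list past camera or with changed members, up to 4 changed members with the largest change, or for a list past camera without such members the 2 with the smallest p. With no descriptions in the tables, an informative name was read as a symbol other than a LOC number, or a LOC number with a synonym; this reading, and the use of the rule on the lists by symbol, came after the files had been opened. Genes named outside it are said to have been chosen after their values were seen.

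The fit was tested on simulated data with the real means and spreads of the 29286 probe sets, with 200 changed in each of 5 runs. It recovered 51.9% of log2 changes of 1, 80.9% of changes of 2 and 95.5% of changes of 3, and 4.75% of its calls were false on average. Simulated values were drawn independently for each probe set and array. They lack the closeness of water 1 and 2 and any other structure shared across probe sets, so these rates need not hold for the real arrays.

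Alternatives covered the filter, normalization, prior, array weights, a replicate block, the thresholds, an ordinary t statistic, 1 mean per gene, and leaving out each array; for lists they also covered an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.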

Results

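The data describe gene expression in the first trifoliolate leaf of soybean plants at the V1 stage, 48 h after that leaf was sprayed. LCO is a lipo-chitooligosaccharide or Nod factor, the class of signal by which rhizobia announce themselves to legume roots. The treated leaves received 2 mL of a solution with 1e-07 M LCO and 0.02% Tween 20, and the control leaves received 2 mL of water with the same detergent. There were 3 arrays per group. Medians of the 61170 deposited log2 values ran from 3.42 to 3.47 per array, and medians of the 29286 tested soybean probe sets from 6.84 to 6.89.

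The first question is how far arrays of a group lie together. The first principal component of the tested probe sets held 56.8% of the variance and separated LCO from water, with scores of -51.96, -51.94 and -21.64 for water 1, 2 and 3 and 32.54, 33.05 and 59.95 for LCO 1, 2 and 3. The second held 26.2% and set water 3 at -48.38 against LCO 1 at 47.99. Water 1 and water 2 were the closest pair: their difference had an SD of 0.198 over the tested probe sets, against 0.341 to 0.695 in the other pairs. Between water 3 and LCO 2 that SD was 0.487, close to the 0.459 between water 3 and water 1.

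**Figure D1:**
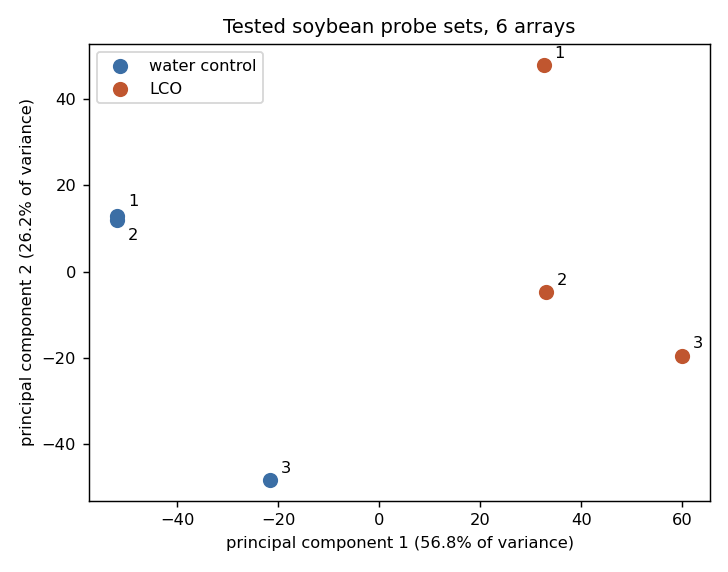
Scores of the 6 arrays on the first and second principal components of 29286 tested soybean probe sets (log2 values; axes in score units, with the share of variance in percent), numbered by replicate and coloured by group. Water 1 and 2 nearly coincide at -51.96 and -51.94 on the first component, water 3 lies at -21.64, and the LCO arrays lie from 32.54 to 59.95.

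The central comparison asks which leaf transcripts differ 48 h after LCO. Among changed genes with an informative name, those of asparagine synthesis, terpene synthesis, phosphatase and chalcone synthase activity were among the 12 largest falls, and the transcription factor gene DREB1-like, the glutathione S-transferase GSTU28, the cytochrome P450 CYP82A3 and the isoflavone synthase IFS1 were among the 12 largest rises. Other glutathione S-transferases, GSTZ3 and GSTU62, were among those 12 falls. In all, 1040 of 29286 probe sets changed, 490 higher and 550 lower with LCO, and 510 of them by at least 2-fold. In each of these 1040 the groups did not overlap, which also held for 31.5% of all tested probe sets, where chance gives 10%. Of the 1040, 320 have 1 gene, 11 several and 709 none in the table used, so most of what changed is unnamed here. The count depends on which arrays are used: it was 199 without water 1, 193 without water 2, 2207 without water 3, 570 without LCO 1, 416 without LCO 2 and 291 without LCO 3, and 203 when water 1 and 2 were averaged, an alternative chosen after seeing the data. Without the 54 probe sets that read as on in a group and off in the other, described among the closing observations, 986 remained.

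**Figure D2:**
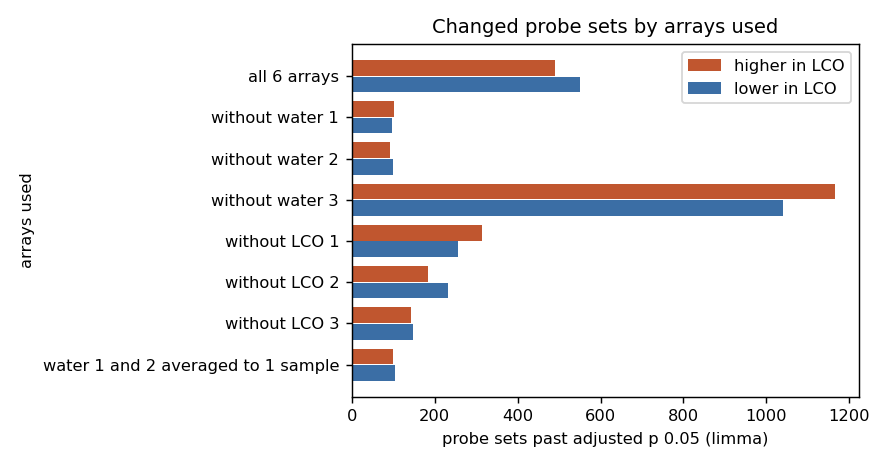
Number of probe sets past an adjusted p of 0.05 in limma, higher (orange) and lower (blue) with LCO, for all 6 arrays, with each array left out, and with water 1 and 2 averaged. The bars for all arrays stand at 490 and 550, those without water 2 at 93 and 100, and those without water 3 at 1166 and 1041.

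Among named genes that fell, NES, a nerolidol synthase of the terpene synthase family, went from 10.31 ± 0.08 in water to 5.96 ± 0.84 with LCO (log2, mean and SD, n = 3), a change of -4.35 (SE 0.39, limma adjusted p = 0.00440). AS2, an asparagine synthetase, had a change of -1.80 (SE 0.10, adjusted p = 5.54e-04) in its brighter probe set and of -4.61 (SE 0.27) in the other. PAP25, a purple acid phosphatase, fell in 3 of 3 probe sets, the brightest by a log2 change of -3.63 (SE 0.29, adjusted p = 0.00257). The log2 change was -2.03 (SE 0.15) for GSTZ3, a zeta-class glutathione S-transferase, -1.83 (SE 0.29) for GSTU62 of the tau class, and -1.76 (SE 0.20) for AGL3L, a MADS-box gene. LCO arrays were at the level of the other organisms' probe sets for iomt2 (LOC100813225), an isoflavone O-methyltransferase gene that was at least 4.15-fold lower. The same held for PTS-L5 (at least 3.69-fold lower), the bZIP factor BZIP94 (at least 3.17-fold) and KNBS1 (LOC547562), listed here with resistance proteins (at least 3.32-fold). A further KNBS1 probe set had the opposite sign, at 1.41 (adjusted p = 0.0654). The 1 other tested probe set of GSTZ3 and the 1 other of BZIP94 were also lower, but did not pass. The probe sets of iomt2 and BZIP94, all 3 of PAP25 and the dimmer of AS2 belong to the 54 that read as on or off.

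Among those that rose, DREB1-like, an AP2 transcription factor of the cold-response type, was at least 8.44-fold higher with LCO, where its SD was 1.15. GSTU28, a tau-class glutathione S-transferase and also among the 54, rose by 2.88 (SE 0.22, adjusted p = 0.00213). CYP82A3, a cytochrome P450, rose by 2.24 (SE 0.41, adjusted p = 0.0408), and KR3, a resistance-protein gene, by 2.18 (SE 0.27, adjusted p = 0.0156). IFS1, an isoflavone synthase, rose by 2.09 (SE 0.25, adjusted p = 0.0140). SIP1-4 and SIP1-3, of the small basic intrinsic proteins in the aquaporin superfamily, rose by 1.35 (SE 0.22) and 1.09 (SE 0.18); the aquaporin lists do not hold these genes. NAC21 (LOC100170714) and NAC19, transcription factors of the NAC family, rose by 1.22 (SE 0.10) and 1.02 (SE 0.11). VTE5 (LOC100793696), a phytol kinase of tocopherol synthesis, rose by 1.03 (SE 0.14), ITPK1, an inositol phosphate kinase, by 0.93 (SE 0.15) and HPPD, which feeds tocopherol and plastoquinone synthesis, by 0.90 (SE 0.10). None of the other tested probe sets of CYP82A3 (2), NAC21 (3), NAC19 (1) and ITPK1 (1) passed, though all had the same sign. The 1 other of KR3 and the 2 others of HPPD also rose.

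Leaving out single arrays ended many of these calls. Of the 53 named probe sets past the threshold, 15 stayed past it with each array left out in turn, among them NES, AS2, PAP25, GSTZ3, GSTU28, NAC21, KNBS1, iomt2, BZIP94 and a CHS1 probe set. The number that stayed was 19 without water 1, 18 without water 2, 47 without water 3, 33 without LCO 1, 32 without LCO 2 and 24 without LCO 3.

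**Figure D3:**
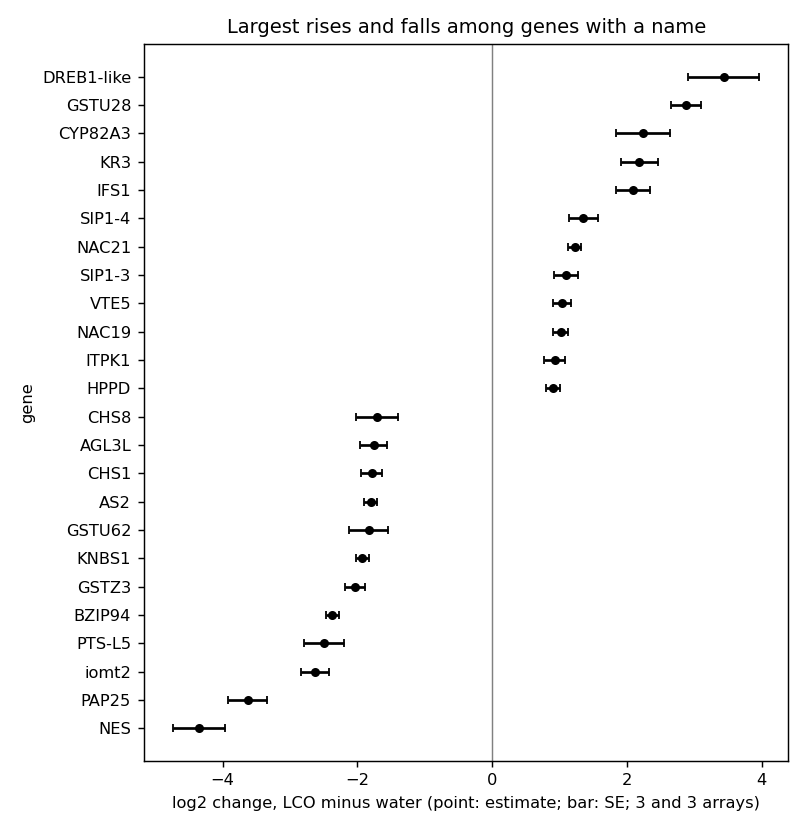
Log2 change, LCO minus water, of the 12 largest rises and 12 largest falls among changed genes with an informative name, 1 probe set per gene. Points are limma estimates and bars their standard errors from 3 and 3 arrays; they run from -4.35 for NES to 3.44 for DREB1-like, and for genes near background in a group the estimate is not a bound.

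Flavonoid and isoflavonoid synthesis, which makes pigments, isoflavones and pterocarpan phytoalexins, was the gene group with the most changed probe sets. In the list by symbol, 15 of 49 probe sets fell, 1 rose and 33 did not pass. Adjusted over the list alone, 23 fell and 2 rose. The 49 probe sets carry 27 gene labels, so a gene can count more than once. Chalcone synthase, the entry enzyme, was represented by CHS1, at least 1.99-fold lower in the brighter of its 2 changed probe sets, and by CHS8, with a log2 change of -1.71 (SE 0.31). The other 3 probe sets of CHS1 did not pass, with changes of -0.81, -0.21 and 0.00. The other 3 tested probe sets of CHS8 were lower too, but did not pass. CHR1, the chalcone reductase that directs flux to deoxyisoflavonoids, went from 9.30 ± 0.22 to 7.71 ± 0.57, a change of -1.60 (SE 0.29). The changes of the glycosyltransferases IF7GT and UGT78K1 were -1.13 (SE 0.18) and -0.98 (SE 0.18), and that of CYP93A1, a hydroxylase of the pterocarpan branch, was -1.10 (SE 0.21). HIDH, the dehydratase that completes the isoflavone skeleton, had a change of -1.25 (SE 0.16) in a probe set chosen after its values were seen. The other 3 tested probe sets of HIDH and the 1 other of CHR1 also fell, while the 1 other of CYP93A1 did not pass. IFS1, a synthase just upstream of HIDH, was the member that rose. The brighter probe set of isoflavone synthase, IFS2, had the opposite sign, from 9.33 ± 0.36 to 8.24 ± 0.83, a change of -1.09 (SE 0.42, adjusted p = 0.170). Each of these genes lists the other's name as a synonym. Many calls of single flavonoid genes ended with 1 array left out. Of 6 such fits, the call held in 1 for IF7GT, UGT78K1 and CYP93A1, and in 2 for CHR1 and CHS8. It held in 3 for the HIDH probe set and 4 for IFS1, and in 6 for iomt2 and the brighter changed CHS1 probe set. The median log2 change of the list was -0.61, or -0.60 with the 4 members that have a group at background held at their bounds. The camera adjusted p was 3.22e-06, which became an adjusted p = 0.859 with an estimated correlation. In the shorter list written before the data were examined, 6 of 24 fell, 1 rose and 17 did not pass, with 8 lower and 1 higher adjusted over the list alone (adjusted p = 0.00524, or adjusted p = 0.549 with an estimated correlation). In the same arrays the 3′ minus 5′ difference of the P450 control gene, a sign of RNA quality, was 0.98 ± 0.03 in water and 2.27 ± 0.60 with LCO. Other controls with a bright 5′ probe set moved less, by 0.21 for GlutTrans and -0.17 for an actin.

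**Figure D4:**
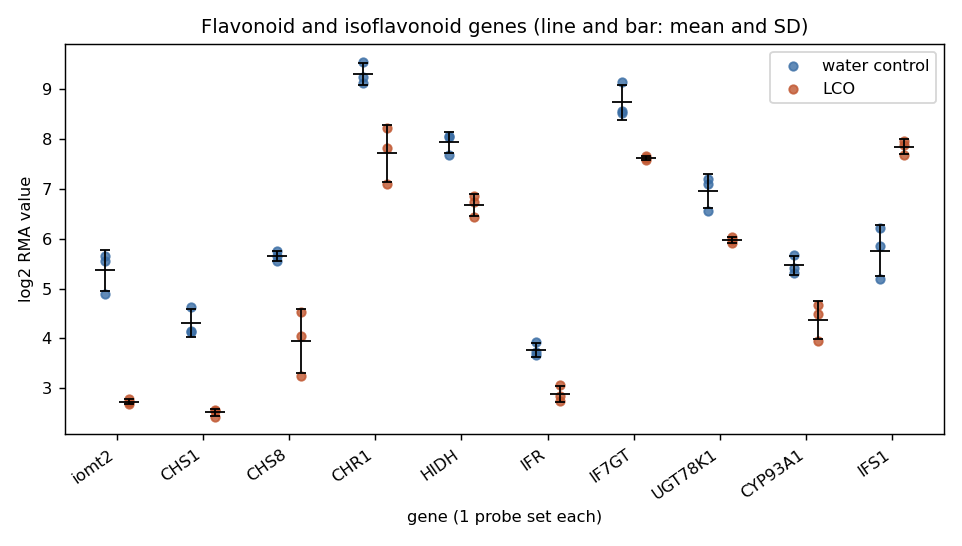
Log2 RMA values of 10 flavonoid and isoflavonoid genes, 1 probe set each, on the 3 water arrays (blue) and 3 LCO arrays (orange), with lines and bars for group means and SDs. The probe sets shown were picked among those that changed, so they do not stand for the list, where 33 of 49 did not pass. The genes other than IFS1 lie lower with LCO, as for CHS8 at 5.66 ± 0.10 against 3.95 ± 0.65, and IFS1 lies higher, at 7.84 ± 0.15 against 5.76 ± 0.51.

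Sieve element occlusion proteins, which plug phloem and mark vascular tissue, made up all 7 probe sets of the vascular list. No member passed over all probe sets tested, while 5 passed as higher adjusted over the list alone. Their median log2 change was 0.74 (camera adjusted p = 0.00524 among the lists written first, or adjusted p = 0.549 with an estimated correlation). SEOF had a change of 0.98 (SE 0.20, adjusted p = 0.0562) and SEO-F3 of 0.88 (SE 0.18, adjusted p = 0.0579). These arrays are also those in which the P450 control's 3′ minus 5′ difference was larger, by 1.29, with LCO, which not all control genes shared.

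Lipoxygenases and jasmonate genes, which make oxylipins, had no changed member among 39 probe sets, also when adjusted over the list alone. Estimates were lower with LCO in 34 of them, with a median of -0.54 (camera adjusted p = 6.18e-04, or adjusted p = 0.859 with an estimated correlation), and the call ended with 1 mean per gene (adjusted p = 0.195; with an array left out it ran from 4.57e-07 to 0.0174). The list's array means overlapped between the groups, with water 3 at 7.91 under LCO 1 at 8.22 (exact permutation p = 0.2). The leaf lipoxygenase LOXB1 had a change of -0.58 (SE 0.13, adjusted p = 0.064) and LOX1.4 (LOC547835) of -1.39 (SE 0.32, adjusted p = 0.0695). The list of vegetative storage proteins and acid phosphatases, the leaf's protein store, held 11 probe sets with only 3 gene labels. LOXB1 stands in it as well as in the lipoxygenase list, and PAP25, which fell, is not in it. Its estimates were lower in 11 of 11, with none past the threshold and 2 lower adjusted over the list alone (median -0.43, camera adjusted p = 0.0148, or adjusted p = 0.549 with an estimated correlation). This call was lost without water 1 (adjusted p = 0.0866) and without LCO 3 (adjusted p = 0.0762). Among the other arrays left out it was at most 0.0249. VSPB (LOC547820), in that list, had a change of -1.58 (SE 0.40, adjusted p = 0.0813). As for the flavonoid genes, the LCO arrays with these values had the larger P450 3′ minus 5′ difference, which not all control genes shared.

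UDP-glycosyltransferases, which attach sugars to small molecules, were lower in 8 of 8 estimates, with IF7GT and UGT78K1 past the threshold and 3 lower adjusted over the list alone (adjusted p = 0.0148, or adjusted p = 0.549 with an estimated correlation). Without LCO 3 the adjusted p was 0.0641, in a range from 0.00451 over the arrays left out. Phenylpropanoid and lignin genes had 1 of 24 probe sets lower past the threshold and 3 adjusted over the list alone (median -0.38, adjusted p = 0.0464, or adjusted p = 0.859 with an estimated correlation); the 1 that passed matches several genes. The array means of this list also overlapped between the groups (exact permutation p = 0.3). This list's call ended without water 1 (0.108), water 2 (0.167), LCO 2 (0.0522) or LCO 3 (0.132), given as adjusted p, and the value was 3.60e-04 without water 3. CYP98A2, a hydroxylase of lignin precursors, had a change of -0.59 (SE 0.13, adjusted p = 0.0664), and 4CL3, a coumarate ligase, of -0.46 (SE 0.10, adjusted p = 0.0632). Pathogenesis-related proteins had a median of -1.39 over 8 probe sets, with none changed and 2 lower adjusted over the list alone (adjusted p = 0.0503). With an array left out its adjusted p ran from 0.00645 to 0.111. This list passed camera with the replicate block (adjusted p = 0.01505) and with water 1 and 2 averaged (0.0217). It did not pass with 1 mean per gene (0.195) or with an estimated correlation (0.859). The same arrays differed in the P450 control's 3′ minus 5′ difference, at 0.98 ± 0.03 in water and 2.27 ± 0.60 with LCO, which not all control genes shared.

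Genes first described in root nodules are of interest because LCO is the signal that starts nodulation. Of 10 probe sets in this list, 2 rose and 8 did not pass (adjusted p = 0.232). Both are of SS, the nodulin-100 sucrose synthase, which also stands in the list of sugar transport and starch genes, where 2 of 26 rose (adjusted p = 0.0648, or adjusted p = 0.859 with an estimated correlation). With an array left out the adjusted p of that list ran from 0.0141 to 0.193, passing without water 1 (0.0141), water 2 (0.0491) or LCO 3 (0.0371). It also passed with no filter (adjusted p = 0.0388), with the replicate block (0.0372) and with water 1 and 2 averaged (0.0271). The larger change of SS was 0.59 (SE 0.10, adjusted p = 0.0305).

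Transcription factor lists did not pass camera's directional test, and their changed members are given singly. Fry's mixed test, open to changes in both directions, called the NAC, bZIP, MYB and ethylene and AP2/ERF lists by symbol, but not WRKY. That test called 31 of the 44 lists by symbol. In the NAC family 3 probe sets rose and 2 fell of 39, and 4 and 2 adjusted over the list alone (adjusted p = 0.644 among the lists by symbol, with a median of 0.08 and a mean of -0.02). The falls were both of NAC32 (LOC100170751), at -1.64 (SE 0.32) for the larger. Of 95 bZIP probe sets 2 fell, BZIP94 and BZIP95, the latter with a change of -0.88 (SE 0.14). Of 89 WRKY probe sets 1, of WRKY22, fell, at -0.71 (SE 0.10), and 1 of 89 also passed adjusted over the list alone. The other 4 tested probe sets of WRKY22 did not pass. None of 87 MYB probe sets passed, nor adjusted over the list alone. Among ethylene and AP2/ERF genes DREB1-like rose and 2 of 24 fell, both of ERF3, at -0.74 (SE 0.12) for the larger; the median of this list was -0.15 and its mean 0.09.

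Glutathione S-transferases went both ways, with 5 of 48 lower and 1 higher, and 10 and 4 adjusted over the list alone (adjusted p = 0.36); GST3 had a change of -1.42 (SE 0.20). In isoprenoid, carotenoid and tocopherol synthesis 4 of 33 rose and none fell, namely the 3 probe sets of HPPD and VTE5 (adjusted p = 0.644, with a median of -0.02 and a mean of 0.07). Single members of other lists also fell, with log2 changes of -1.70 (SE 0.22) for HSP17.5-E, a small heat shock protein, -0.93 (SE 0.12) for NIP1-8, the 1 of 28 probe sets of the aquaporin list that passed, -0.75 (SE 0.14) for FVE, -0.57 (SE 0.11) for FAD2-2, an oleate desaturase, and -0.50 (SE 0.10) for the 14-3-3 protein GF14C. The calmodulin-binding IQD45 rose by 0.84 (SE 0.12), GASA32 by 0.57 (SE 0.11), ALDH5F2 by 0.55 (SE 0.09) and OAS-TL6 of cysteine synthesis by 0.53 (SE 0.09). The calls of FVE, FAD2-2, GF14C and OAS-TL6 were lost whichever array was left out. The 1 other tested probe set of each of these genes did not pass. CYP82A4 (LOC100778056) was at least 1.91-fold lower and ALDH3H1 at least 1.46-fold. None of 23 photosynthesis probe sets passed (median 0.06, adjusted p = 0.334).

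Over the lists, 4 of the 17 written first and 4 of the 44 by symbol passed camera. These overlap: flavonoid synthesis passed in both, and the vascular list holds the same 7 probe sets as the sieve element list by symbol. IF7GT and UGT78K1 count for the UDP-glycosyltransferase list and for the flavonoid list by symbol. With an estimated correlation or with fry's directional test 0 of either passed, while fry's mixed test called 13 and 31. Other ways to part the 6 arrays into 3 and 3 gave up to 7 and 18 lists past camera, and each of these keeps part of the difference between LCO and water. Passing camera was therefore not particular to the real grouping.

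Probe sets of the other organisms were taken as background. Of 23394, 2 were higher and 1 lower with LCO (limma, adjusted p under the threshold), while 2008 had an unadjusted p under 0.05. That is a larger share than the 0.05 that would arise on average if no probe set differed. The RNA quality controls did not all move with the groups. In the P450 control gene, the 3′ minus 5′ difference was 0.98 ± 0.03 in water and 2.27 ± 0.60 with LCO (log2, mean and SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allow). The same difference in the GlutTrans control was 0.39 ± 0.35 and 0.60 ± 0.27 (exact p = 0.4). The P450 3′ minus middle difference was 0.98 ± 0.01 and 1.33 ± 0.17, higher in 3 of 3 LCO arrays (exact p = 0.1). For actin, the 3′ minus middle difference was 1.65 ± 0.20 and 1.69 ± 0.12 (exact p = 0.8), and in a further actin control the 3′ minus 5′ difference was 1.48 ± 0.13 and 1.31 ± 0.05. For SucBP, whose 5′ probe set averaged 2.05 and so lay under the background level, that difference was 0.41 ± 0.05 and 0.70 ± 0.23, higher in 3 of 3 LCO arrays. The first actin control and ubiquitin also had a 5′ probe set under that level, and their groups overlapped. Their 3′ minus 5′ differences were 5.38 ± 0.02 and 5.50 ± 0.25 for actin and 0.60 ± 0.19 and 0.70 ± 0.27 for ubiquitin. The 24 Bacillus subtilis poly-A control probe sets above background, for transcripts spiked into the samples, averaged 6.33 ± 0.15 in water and 6.77 ± 0.06 with LCO (exact p = 0.1).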

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

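The counts of splits, the comparisons of control probe sets and the tests of explanations in this part were chosen after the results had been seen; the limma fit of the other organisms' probe sets was not. Among signals outside the main measurement, 4 that were higher with LCO were flagged. The P450 3′ minus middle and SucBP 3′ minus 5′ differences given earlier were also higher in 3 of 3 LCO arrays, but were not checked for this flag. A probe set of the nematode H. glycines was higher with LCO by 1.30 (SE 0.16, limma adjusted p = 0.019), and the oomycete ribosomal probe set Psojae_rRNA_347_at by 1.403 (SE 0.20, adjusted p = 0.0499). Among the 10 splits of the arrays into 3 and 3, only 1, the real one, reached its count of 3 changed probe sets of the other organisms, and the highest other gave 1. These splits are too few for a share under 0.05. The P450 control gene's 3′ minus 5′ difference was larger with LCO by 1.29, in 3 of 3 arrays above all water arrays. The poly-A controls were brighter with LCO by 0.43 on average, again in 3 of 3 arrays.

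The flavonoid and isoflavonoid list was lower with LCO, with a median of -0.61 over 49 probe sets. Probe sets that read as on or off do not carry it: only iomt2 of the 15 that fell is among them, and the median without them was -0.61, with a median absolute deviation of 0.55. Loss of 5′ ends of RNA in the LCO samples could lower some probe sets, but the control genes with a bright 5′ probe set went apart, at 1.29 for P450, 0.21 for GlutTrans (the median) and -0.17 for an actin, and the position of each flavonoid probe set in its transcript is unknown, so this stays open. Variation between samples in genes that move together also stays open: the call is lost with an estimated correlation (adjusted p = 0.859), although the list's mean on each of the 3 LCO arrays lies under that on each of the 3 water arrays (exact p = 0.1, the smallest that 3 against 3 allow), and the list also passed camera in 4 of the 9 other splits (lowest adjusted p = 1.52e-05), each of which keeps part of the difference between LCO and water. A response to the spray is the design's own explanation and was not separated from these.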

How the results depend on the processing

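Averaging water 1 and 2 and leaving out the all-or-none probe sets were chosen after seeing the data. The lists by symbol were written after the files had been opened and the symbols read, but before any test. Counts of changed probe sets (higher and lower in parentheses), against 1040 (490 and 550), were 9544 (5017 and 4527) with array weights, 510 (262 and 248) at 2-fold, 3030 (1412 and 1618) at an adjusted p of 0.10, 193 (96 and 97) with an ordinary t statistic, 260 (103 and 157) with 1 mean per gene and 203 (99 and 104) with water 1 and 2 averaged. The fold, threshold and gene-mean counts follow from how those settings are built. Averaging any other pair of a group left 419 to 684, so construction alone does not give 203; for array weights and the ordinary t statistic the cause was not tested. Array weights put water 3, LCO 1 and LCO 3 at 0.362, 0.360 and 0.568 and the others above 2. Leaving out 1 array gave 193 to 2207 changed, 93 to 1166 higher and 97 to 1041 lower. No filter, a stricter filter, either re-scaling, an intensity trend or a robust prior gave counts from 964 to 1137.

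With the replicate block the count was 3010 (1515 and 1495), 1036 of them among the 1040, and 10 lists by symbol passed instead of 4. Whether same-numbered arrays pair stays unsettled. Their deviations from the group means correlated, across probe sets, at 0.452, -0.0359 and 0.527 for numbers 1, 2 and 3. Between LCO and water arrays of unlike number this correlation ran from -0.542 to 0.448.

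Lists past camera, against 4 written first and 4 by symbol, were 7 written first without a filter, 2 by symbol with 1 mean per gene, and 0 and 0 with an estimated correlation and 0 and 0 with fry; with 1 array left out they ran from 2 to 7 and from 3 to 9. No named gene and no listed shift changed sign under any setting run. Under settings other than leaving out an array, 433 values of named probe sets kept their side of the threshold, 34 fell short of it, 33 of these with water 1 and 2 averaged, and 13 came to pass it. That averaging kept 20 of the 53 named calls. With an array left out, 211 kept it, 4 came to pass it and the rest fell short. Signal over the other organisms' level limits the folds of genes whose dimmer group lies under 3.31.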

Other observations

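The counts of splits and the tests of explanations in this part were chosen after the results had been seen, and so were the probe sets of this paragraph; the limma fit and the lists written first were not. The largest rise was in a probe set with no gene in the table used, from 3.37 ± 0.15 in water to 12.61 ± 0.38 with LCO, a log2 change of 9.25 (limma adjusted p = 2.81e-05). A probe set whose identifier differs from it in the cluster's last number had a change of 0.00. For LOC100500577, 1 probe set was at least 103-fold lower and another at least 227-fold higher with LCO, each with the dimmer group at background in 3 of 3 arrays. A further probe set of this gene rose by 2.23 (SE 0.39, adjusted p = 0.0381).

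Probe sets that read as all-or-none, the largest rise among them, were counted. Those with a gap over 2 between groups and a range under 1 within each numbered 54, 27 higher and 27 lower with LCO, against 1 in the highest other split of 3 against 3. Plants or harvests that differ apart from the spray could give such probe sets: water 3 alone stood apart from the other 5 arrays in 24, none of which the spray separates, although a single array has no range to exceed. A sequence variant read by single probe sets was tested on the 7 with an unlike probe set of the same gene, where the median share of the change seen there was 0.35, against 0.411 in 13 other probe sets changed at least 4-fold and 0.619 in 67 changed at least 2-fold (permutation p = 0.34 against the latter), so it cannot be told from a response of single transcripts. Linked blocks of genes were tested under 5 definitions of separated groups, none of them the one that gave the 54. The 2 with gaps over 1 and over 0.8 had more neighbours along the gene order than chance (permutation, adjusted p = 0.025 and 0.025). For the others the adjusted p was 0.0933, 0.122 and 0.512. A gap over 2, the strictest, had 1 pair among 20 genes. Looser gaps do not stand for the 54, so this is not settled either.

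The count of 1040 changed probe sets was the highest of the 10 splits, reached by 1, with 27 in the highest other; 10 splits are too few for a share under 0.05. For the lists, 7 of 10 splits gave as many of those written first and 10 of 10 as many of those by symbol, with 7 and 18 in the highest other. Passing camera at the preset correlation was therefore not particular to the grouping into LCO and water. Each other split keeps part of the difference between LCO and water, so these counts do not separate an effect of the groups, a structure of the samples and a preset correlation that is too low. The count may rest on the closeness of water 1 and water 2: averaging them left 203, against 419 to 684 for the other pairs of a group. Whether they are separate plants stays unknown.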
